A study of Arabidopsis thaliana with 4 samples.

How the data were processed

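The values analysed were array signals of 4 Affymetrix ATH1 GeneChips, 2 from control and 2 from chitosan-treated Arabidopsis seedlings, with 1 value per probe set. Groups and replicate numbers came from the sample titles. The labels' treatment text mentions chitosan for the control samples too, but the titles and the series design name them as controls. Per the labels' protocols, total RNA was extracted with a column kit and labelled by the manufacturer's standard procedure. The dose of 150 µg/ml is that of the series design text.

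The deposited values are intensities on a linear scale, given to 1 decimal and running from 0 to 6653. The submitters' processing notes name GCRMA, with no version or settings. The values do not have the form that method usually gives, since they are not on a log2 scale and the arrays' distributions are not equal. Each array's 2% trimmed mean was 100.01, the pattern left by scaling every array to a common target, so how the authors summarised the probes stays unknown. Such scaling sets the average signal of every array equal and can turn a rise of many bright transcripts into an apparent fall of dim ones. The analysis had been laid out for log2 values, with linear values to be put on log2 first, and this was done. Signals under 1 were set to 1 before log2, a floor chosen after the value range was known and before any test was run. Scanner images and detection calls were not analysed here.

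Of the 22746 probe sets other than control spots, the platform annotation gave 1 gene for 13513, several for 503 and none for 8730. Those with none are unnamed here rather than without a gene. Symbols were updated through gene identifiers with a TAIR10.1 gene table, which matched 13436 probe sets and was used for names only. No genes were named from probe sets with several. No coordinates are given, since the files name no genome build.

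Probe sets with a mean log2 signal of at least 4 over all 4 arrays were tested, 14329 in all. Chitosan was compared with control by limma (version 3.58.1, lmFit and eBayes, 2-sided, R 4.3.3) with no block. P-values were adjusted by the Benjamini-Hochberg method over all probe sets tested, with a threshold of 0.05. A permutation of 2 against 2 arrays cannot reach that threshold, so limma's moderated variance, with a prior worth 3.58 degrees of freedom, carries the tests. Folds are differences of mean log2 signals. Where a group's mean signal was under 16, the fold is a bound: the brighter group's mean divided by 16. Both the floor and this bound are on the authors' scale.

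Gene lists were compared with all other genes by camera (limma, preset correlation 0.01), using for each of 7641 genes the probe set with the highest mean. Lists with at least 5 genes tested were adjusted together. camera with an estimated correlation and fry were run beside it. The 27 lists, the tests and the rule for named genes were fixed before the data were examined. That rule took, among called single-gene probe sets with the chitosan arrays on one side of both controls, the 15 largest rises and 10 largest falls. It added up to 4 genes with the smallest adjusted p of each list that passed and up to 2 of each other list. Genes outside the rule were chosen after their values were seen. These are ChiC, AT4G16260, XTH18, GSTU26, UGT73B4, UGT73B5, WRKY22, PUB22 and PUB23 and the genes of the closing section.

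A further 20 gene families were gathered by symbol from the annotation, before any gene's value was looked at. The symbol patterns of 2 families were corrected after their values had been seen, because they had also taken genes of other kinds. This removed 4 cyclophilins from the cytochromes P450 and 2 peptide deformylases from the defensins, and moved the camera adjusted p of the defensins from 0.027 to 0.0939. Lists of class III peroxidases, jasmonate oxidases, iron-deficiency-induced genes, iron-sufficiency genes and root tissue markers were written by locus after the largest changes had been seen.

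The fits were tested on simulated data with the real means of the 14329 probe sets. Each spread was drawn at random from the estimated spreads of probe sets with a similar mean. Of 100 probe sets changed by 1 on the log2 scale 57 were recovered, and of 100 changed by 2 on the log2 scale 86 were recovered, with 4 unchanged probe sets called. A simulated list of 9 genes moved by 1 was called and 0 of the others were. Only 200 probe sets were changed in the simulation, far fewer than the 1860 higher and 3145 lower in the data. Its genes also varied independently. These rates therefore do not carry over to the data, and the list result does not cover correlated genes. Alternatives planned in advance were no filter, a mean log2 of at least 6, a variance trend with and without robust estimation, quantile normalization, centring each array on its median, leaving out each array, a replicate block, a fold minimum, a fold rule with no test, camera with an estimated correlation and the mean of a gene's probe sets. Floors of 16 and 0.1 and log2 of the signal plus 16, and an estimated correlation for the lists without the filter, were added after seeing the data. Tables and plots were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.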

Results

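Transcripts were measured on 4 Affymetrix ATH1 arrays, each hybridised with biotin-labelled RNA from whole Arabidopsis thaliana seedlings of the Columbia ecotype. The seedlings were 4 days old and grew in liquid half-strength Murashige and Skoog medium with 30 mM sucrose under continuous light. Arrays 1 and 2 of the chitosan group came from seedlings exposed for 3 h to chitosan at 150 µg/ml, and the 2 control arrays came from seedlings given only the solvent. Chitosan is the deacetylated form of chitin, the polymer of fungal cell walls and arthropod shells. Each array held 22810 probe sets, 64 of them control spots, with linear signals scaled by the authors. Median signals were 37.0 and 37.1 on the control arrays and 33.2 on each chitosan array. Over the 14329 probe sets tested, log2 signals correlated across probe sets at 0.994 between the control arrays and at 0.986 between the chitosan arrays, against 0.886 to 0.890 between groups. The 3′/5′ signal ratio of actin, a measure of RNA integrity, was 2.31 and 2.34 in the controls and 2.15 and 2.01 with chitosan. The ratios of GAPDH (0.879 and 0.928 against 0.968 and 0.923) and ubiquitin (1.26 and 1.15 against 1.17 and 1.21) overlapped between the groups. Hybridization spike-ins were brighter on chitosan array 2 than on the other 3 arrays, at a median of 1.35 times the control mean. The labels do not say whether the arrays of a group came from separate cultures, so all p-values measure only the spread between these arrays, which may be technical, and the number of arrays limits the precision.

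The single comparison of the design asks which transcripts differ between seedlings exposed to chitosan for 3 h and their solvent controls. A treatment time was assigned to the chitosan arrays only, so a difference in harvest time cannot be excluded. Among the lists of genes followed, 6 of the 9 chitinases and β-1,3-glucanases tested were higher and 2 lower. On the early immune signalling list the 4 genes tested of 30 were higher, the kinase BIK1 and the ubiquitin ligases PUB22, PUB23 and PUB24. The 5 heat shock genes tested, of 25 listed, and 6 of the 9 expansins and xyloglucan-modifying enzymes tested were lower. Large rises included those of berberine bridge enzyme-like oxidases, the defensin PDF1.2 and the cinnamoyl-CoA reductase CCR2, and large falls those of some class III peroxidases and jacalin-related lectins. Of 21 class III peroxidases tested, on a list written after these changes were seen, 11 were lower and 6 higher. Among 3 other jacalin-related lectins, tested by symbol, 1 was lower, JAL22 by 1.32-fold. In total 1860 probe sets were higher and 3145 lower with chitosan (limma, adjusted p under 0.05), of which 727 and 714 changed at least 2-fold and 253 and 154 at least 4-fold. The called falls were smaller at the median, 0.69 on the log2 scale against 0.79 for the rises. Probe sets assigned to a single gene accounted for 894 of the rises and 1661 of the falls. Among all probe sets tested, 28.5% had both chitosan arrays above both controls and 42.8% had both below, where chance gives 16.7% each way. The counts depended on the arrays used: they were lower with either control array left out and higher with either chitosan array left out. In such a fit the spread is estimated from the complete group alone. They also rested on the filter: with dim probe sets kept, 1188 were higher and 1490 lower. Falls made up 62.8% of the calls as deposited but 51.2% after each array was centred on its median, with 2320 higher and 2436 lower.

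The 15 largest rises and 10 largest falls among single-gene probe sets were ranked by the fitted log2 difference, which for most of them rests on a group mean under 16, so the set and its order depend on near-background values. The rises began from dim control signals. AT1G26380 and AT1G26420, both berberine bridge enzyme-like oxidases, went from 10.8 ± 2.1 to 767 ± 43 and from 5.65 ± 0.35 to 192 ± 7.8 (mean signal ± SD, n = 2 arrays here and throughout). Signals under 16 were treated as near background, so these rises are given as bounds, at least 47.9-fold and at least 12-fold (adjusted p = 3.68e-05 and 3.06e-05). The defensin PDF1.2 (AT5G44420), a marker of jasmonate and ethylene signalling, rose from 13.6 ± 3.6 to 483 ± 28, at least 30.2-fold (adjusted p = 6.60e-05). PDF1.2b (AT2G26020) rose at least 20.8-fold, but its probe set is of the kind that can also bind near-identical transcripts, so these defensins cannot be separated with certainty. CCR2 (AT1G80820), a cinnamoyl-CoA reductase of monolignol synthesis, rose at least 20.7-fold, from 10.2 ± 0.64 to 330 ± 30. AT3G23550 and AT2G04070, both transporters of the MATE efflux family, increased 44.3-fold to 746 ± 91 and at least 12.1-fold to 194 ± 2.3. The control signals of AT3G23550, 15.7 and 17.9, lay on both sides of 16, so its fold is uncertain too. AT5G05600 (20.9-fold, to 566 ± 27) and AT2G38240 (at least 6.2-fold, to 99.2 ± 8.3) encode 2-oxoglutarate-dependent oxygenases that hydroxylate jasmonate. The remaining large rises were AT4G36700 (at least 14.1-fold), AT1G57630, which encodes a TIR-domain protein (at least 11.9-fold), AT1G10585, a basic helix-loop-helix factor (at least 13.8-fold), AT4G22470 (28.7-fold), AT2G22880, a VQ-motif protein (at least 15.1-fold), and AT1G68620 (at least 8.0-fold).

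Peroxidases, lectins and a small heat shock protein made up 6 of the 10 falls ranked largest. All 10 had a chitosan mean under 16, and some genes outside this set, such as the small heat shock protein AT1G53540 (10.6-fold), fell by more than the bound of several of them. The class III peroxidases AT4G26010, AT5G17820 and AT3G01190 dropped from 596 ± 15, 369 ± 5.2 and 184 ± 5.6 to signals of 4.95, 1.85 and 2.75, which is at least 37.3-fold, 23.1-fold and 11.5-fold lower (adjusted p = 0.000268, 0.000226 and 0.00165). The jacalin-related lectins AT1G52070 and AT1G52060 were at least 13.1-fold and 9.8-fold lower. The small heat shock protein AT1G52560 was at least 5.8-fold lower, although its chitosan arrays differed widely (5.85 ± 8.0). The other genes of this set, AT1G14960, AT5G54370, AT3G22570 and AT5G10130, were at least 16.4-fold, 12.8-fold, 11.4-fold and 5.9-fold lower. Without the filter on dim probe sets, 6 of these 25 genes missed the threshold at adjusted p between 0.0552 and 0.159: AT4G36700, AT1G57630, AT3G01190, AT1G52060, AT1G52560 and AT3G22570.

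**Figure D1:**
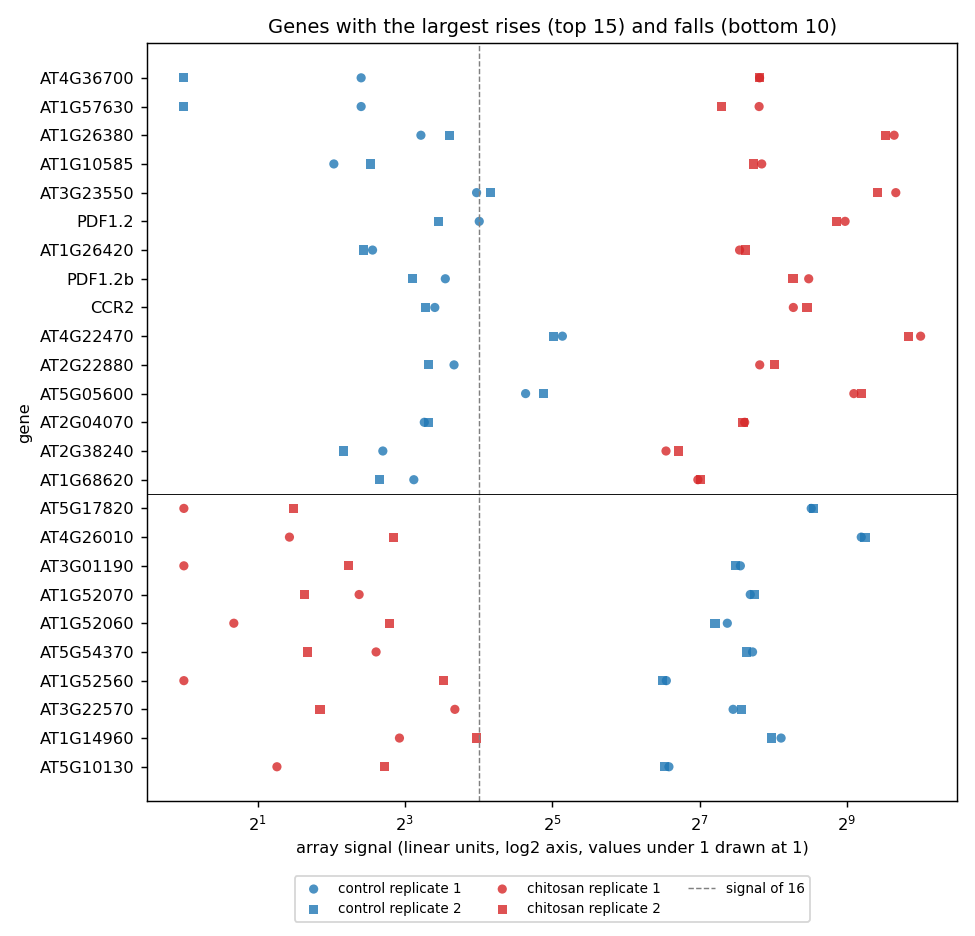
Array signal on a log2 axis (linear units, values under 1 drawn at 1) of the 15 genes with the largest rises, above the line, and the 10 with the largest falls, below it; each point is 1 array, blue for control and red for chitosan. Every gene has both chitosan arrays on the same side of both controls, and the dim side of most genes lies under the dashed line at a signal of 16.

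Gene groups were followed with 27 lists fixed before the data were examined. Probe annotation reached 92 of their 552 loci, so 5 lists had the 5 tested genes needed for a set test and the others are described by their members. Chitinases and β-1,3-glucanases shifted upward as a list (9 of 18 listed genes tested, 6 higher, 2 lower, median log2 change 0.77, camera adjusted p = 0.00156, or 0.187 with an estimated correlation). The only β-1,3-glucanase tested, AT4G16260, rose 3.34-fold, and the other genes tested were chitinases. The chitinase CHI (AT2G43570) rose at least 10.4-fold to 167 ± 7.5, AT2G43620 rose 5.48-fold from 332 ± 1.4 to 1819 ± 32, and AT3G47540 rose 4.19-fold to 319 ± 30. Another chitinase, AT2G43610, fell 5.47-fold, from 186 ± 3.3 to 34.0 ± 2.6 (adjusted p = 9.76e-05), and ChiC (AT4G19810) fell 1.64-fold. The upward call of the list was also lost with a stricter filter on dim probe sets (adjusted p = 0.0836), and under the other alternatives its adjusted p was at most 0.00512.

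Heat shock genes fell in all 5 members tested (median log2 change −1.31, camera adjusted p = 0.00156; adjusted p = 0.187 with an estimated correlation). The cytosolic small heat shock protein AT1G53540 dropped 10.6-fold, from 363 ± 7.7 to 34.4 ± 3.5, and AT2G29500 dropped 2.48-fold, from 470.5 ± 13 to 191 ± 22. ATHSP22.0 (AT4G10250), an endoplasmic reticulum small heat shock protein, was at least 5.9-fold lower. AT5G48570, a heat-inducible immunophilin, fell 1.89-fold to 369 ± 28. Expansins and xyloglucan endotransglucosylases, which loosen and remodel the wall of growing cells, also shifted downward (9 tested, 6 lower, 0 higher, median −0.81, camera adjusted p = 0.00464; adjusted p = 0.187 with an estimated correlation). XTH19 (AT4G30290) fell 4.74-fold from 676 ± 15 to 143 ± 8.6, XTH16 (AT3G23730) fell 2.02-fold, and XTH33 (AT1G10550) and the expansin EXPA8 (AT2G40610) were at least 2.2-fold and 2.5-fold lower. XTH18 was level at 975 ± 32 and 977 ± 62 (adjusted p = 0.990). With an estimated correlation no list passed. fry, which asks only whether a list's genes move on balance one way, gave adjusted p = 0.00296, 0.00296 and 0.00379 for these 3 lists. It also passed the glutathione transferase list (adjusted p = 0.0128) and did not pass the photosynthesis list (0.102). The estimated correlation of the glutathione transferase list was negative (−0.05), yet its unadjusted camera p rose from 0.0531 to 0.183 when it was used. Misses with an estimated correlation therefore cannot show whether correlated genes made the calls.

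Glutathione transferases and detoxification genes split in direction (8 tested, 3 higher, 2 lower, camera adjusted p = 0.0664), with a median of 0.32 and a mean of 0.02. GSTU22 (AT1G78340) and GSTU25 (AT1G17180) fell 11.6-fold and 4.74-fold, from 190 ± 4.1 to 16.8 ± 4.5 and from 321 ± 0.49 to 68.0 ± 8.3, while another glutathione transferase, GSTU26, and the glycosyltransferases UGT73B4 and UGT73B5 rose 2.43-fold, 3.29-fold and 4.48-fold. The chitosan signals of GSTU22, 13.6 and 19.9, lay on both sides of 16, so its fold is uncertain. Nuclear-encoded photosynthesis genes, taken as markers of green tissue, had 3 of 7 members lower and 0 higher (median −0.26). The list did not pass (camera adjusted p = 0.207; adjusted p = 0.666 with an estimated correlation), but without chitosan replicate 2 its adjusted p was 0.0478, the lowest over all alternatives, which reached 0.666. LHCB4.2 (AT3G08940), a light-harvesting protein, fell 2.07-fold from 3215 ± 47 to 1554 ± 161, and phosphoribulokinase, PRK (AT1G32060), fell 1.67-fold from 2841 ± 34 to 1707 ± 101. Of the other tissue markers, the root and hypocotyl β-glucosidase PYK10 (AT3G09260) measured 3646 ± 220 and 3510 ± 528 (adjusted p = 0.757). The root hair expansin EXPA18 (AT1G62980) was at least 2.7-fold lower (adjusted p = 0.000348), and isocitrate lyase, ICL (AT3G21720), an enzyme of seed reserve mobilisation, rose 1.33-fold (adjusted p = 0.0456), a call lost without either control or chitosan replicate 1 (adjusted p up to 0.278).

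**Figure D2:**
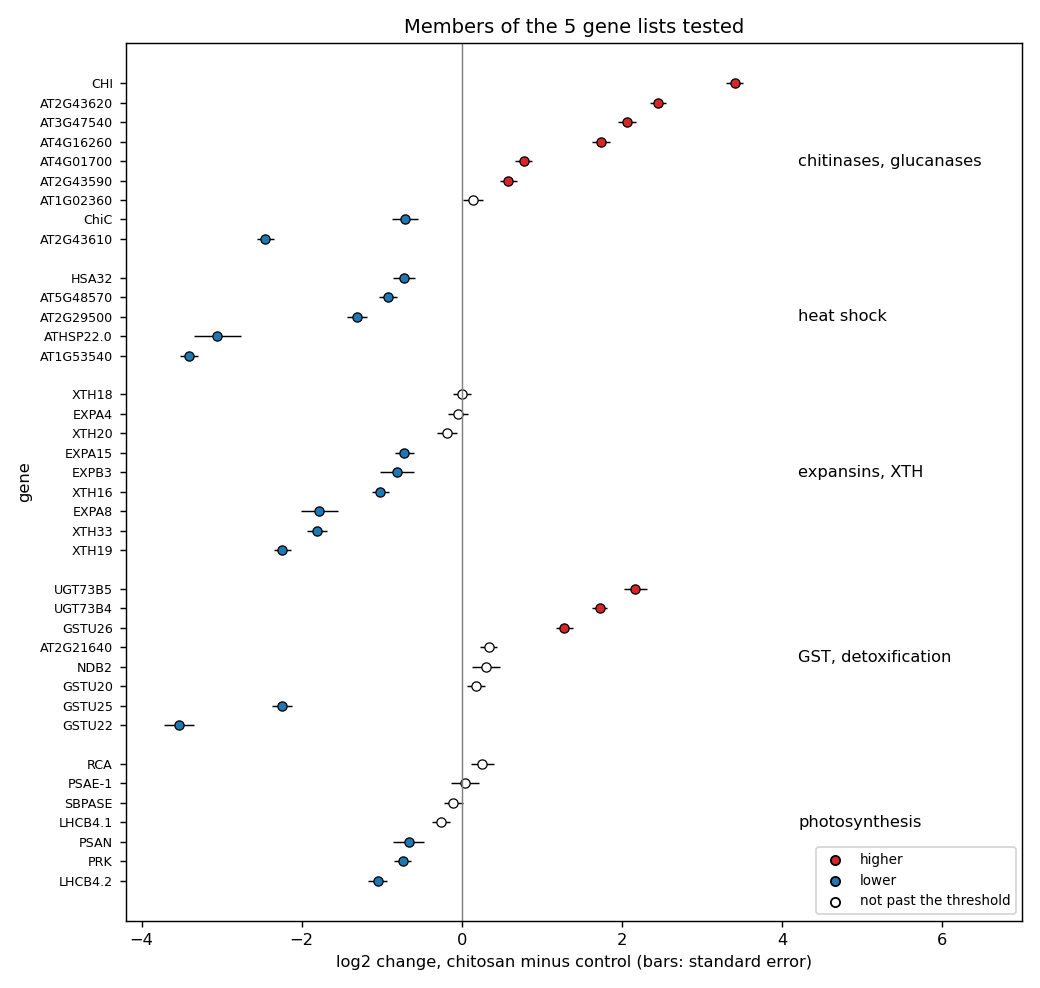
Log2 change, chitosan minus control, of each gene in the 5 lists that could be tested; bars are standard errors, filled points passed adjusted p under 0.05 (red higher, blue lower) and open points did not. All 5 heat shock genes tested lie below 0, no expansin or xyloglucan gene passed above 0, and the chitinase and glutathione transferase lists hold genes called in both directions.

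Several lists with fewer tested genes held only rises among their calls. All 4 genes tested of the list of chitin perception and early immune signalling were higher, but none of them encodes a chitin receptor. With no filter on dim probe sets the list had 5 genes and passed upward (camera adjusted p = 1.63e-05), but not with an estimated correlation (adjusted p = 0.159). BIK1 (AT2G39660), a kinase that acts directly below pattern receptors, rose 2.94-fold from 120 ± 5.9 to 354 ± 8.0, and the ubiquitin ligase PUB24 (AT3G11840), a negative regulator of pattern-triggered responses, rose 3.00-fold to 61.5 ± 2.4. WRKY6 and WRKY53 rose 2.66-fold and 2.92-fold (adjusted p = 0.000457 and 0.000524). WRKY22, the only other gene tested of the 25 on the WRKY list, had a log2 change of 0.47 (adjusted p = 0.0849). Both measured genes of tryptophan and indole glucosinolate synthesis rose, the indole-3-glycerol phosphate synthase AT2G04400 by 5.55-fold to 1437 ± 89 and UGT74B1 (AT1G24100) by 1.92-fold. OPCL1 (AT1G20510), of jasmonate synthesis, rose 2.71-fold from 102 to 277 ± 8.6. The glutaredoxin GRX480 (AT1G28480) and SAG101 (AT5G14930), both of the salicylate list, rose at least 4.7-fold and 2.33-fold. HCT (AT5G48930), of monolignol synthesis, rose 2.18-fold to 1279 ± 150, the zinc finger factor STZ (AT1G27730) rose 4.36-fold to 499 ± 37, and glutathione reductase GR1 (AT3G24170) rose 2.02-fold to 929 ± 66.

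In other lists too small for a set test, single genes fell or no gene was called. The lactate dehydrogenase AT4G17260, of the low-oxygen list, fell 2.83-fold from 578 ± 37 to 205 ± 16. The dehydrin COR47 (AT1G20440) fell 1.83-fold, the clock gene GI (AT1G22770) 1.70-fold, and the auxin-conjugating enzyme WES1 (AT4G27260) 1.44-fold (adjusted p = 0.0169; 0.0847 and 0.134 without control replicate 1 and 2). The kinase AUR2 (AT2G25880), of the cell cycle list, fell 1.40-fold (adjusted p = 0.0442), a call that was lost after quantile normalization or median centring (adjusted p = 0.0770 and 0.0688), without control replicate 1 or 2 (0.0892 and 0.242) and without chitosan replicate 2 (0.0965). Over all alternatives its adjusted p ran from 0.0169 to 0.242. No call was made for the 3 flavonoid genes, with DFR at 69.1 ± 3.3 and 76.0 ± 12 and UGT78D2 at 331 ± 38 and 308 ± 34 in control and chitosan. Log2 changes were −0.11 for BCAT4 of aliphatic glucosinolate synthesis, 0.32 for EIN3 of ethylene signalling (adjusted p = 0.0566), 0.38 for LTI30 of the drought list (adjusted p = 0.0508), 0.07 for CML38 of the touch list, −0.09 for AT3G10040 of the low-oxygen list, −0.26 for LBD16 of the auxin list and −0.28 for AUR1. Without the filter on dim probe sets, the calls of SAG101, EXPA8, GI, WES1, AUR2 and ICL were lost (adjusted p from 0.0550 to 0.158). EIN3 and LTI30 passed under some alternatives, with adjusted p over all alternatives from 0.0136 to 0.354 and from 0.0165 to 0.353, and AUR1 passed with the stricter filter alone (adjusted p = 0.0477, against up to 0.495 under the others). Adjusted over the list alone, the counts were the same except for 1 more higher gene each in the WRKY, ethylene, glutathione transferase and drought lists. The brassinosteroid and gibberellin, cytokinin and aquaporin lists had 0 genes tested.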

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

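The tests in this part were planned before their results were seen, apart from the use of median centring to judge the source of the balance. Hybridization spike-ins, bacterial transcripts added in fixed amounts just before hybridization, lie outside the comparison of the report. Their median signal on chitosan array 2 was 1.35 times the control mean, with 18 of 18 probe sets above it. On chitosan array 1 the median was 0.885 times the control mean, with 0 of 18 above. Poly-A spike-ins, which are added before labelling, were at 0.873 on chitosan array 2 and 1.00 on chitosan array 1.

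More probe sets fell than rose with chitosan, and the balance differed with signal. With a mean log2 signal of 4 to 5, 599 were lower and 288 higher (median log2 change of all tested −0.19); at 5 to 6, 844 were lower and 354 higher (−0.17); above 9, 200 were lower and 221 higher (0.07). Without chitosan array 2, falls made up 63.2% of the calls, and without chitosan array 1 63.9%, against 62.8% with all arrays, which argues against the spike-in difference of array 2 as the source. After quantile normalization falls made up 54.4% of the calls, and after each array was centred on its median, which moves all its probe sets alike, 51.2%. The 54.4% was low enough to meet the limit set in advance for an intensity-dependent shift. The comparison with median centring was not part of that rule. Both adjustments draw the balance toward even whatever its source, so these shares single out none. The authors' scaling can also turn a rise of many bright transcripts into an apparent fall of dim ones. An intensity-dependent shift left by that scaling therefore cannot be told apart from such a rise or from a true loss of many dim transcripts. Neither the rise nor the loss under chitosan was tested.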

How the results depend on the processing

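The floors of 16 and 0.1, the added constant of 16 and the estimated correlation without the filter were chosen after seeing the data; the other settings were planned. Across settings, 0 of the calls shared with the reported fit changed sign. All settings reused these arrays, and every called probe set had its groups fully separated. A change of sign was therefore hardly possible, and the count is no separate support for the calls. Without the filter, 1188 probe sets were higher and 1490 lower, with 22746 tested, and 2 lists were higher, the immune signalling list now having 5 genes; with an estimated correlation as well, its adjusted p was 0.159. Requiring at least 2-fold left 727 and 714, and 2-fold in all 4 pairings of arrays with no test gave 616 and 478. With one array left out, counts ran from 1112 to 2102 higher and 1582 to 3715 lower; the low values came without either control, where the lone control is assumed to vary like the chitosan arrays. Lists ran from 1 to 1 higher and 2 to 3 lower. The stricter filter left 3 lists with enough genes and 0 called in either direction; the heat shock and expansin lists were then too small for the test. With an estimated correlation 0 lists were called higher and 0 lower, against 1 and 2. The replicate block gave 1742 higher and 3102 lower and the same 1 and 2 lists; same-numbered arrays did not deviate together (r = −0.02 across probe sets), so the numbers are not taken as pairs. With the block, AUR2 and ICL no longer passed (adjusted p = 0.0534 and 0.0642). Of the 70 named genes, 58 kept their side of the threshold without the filter and 67 to 70 under the other settings that tested all of them; the stricter filter tested 36 and kept 33. AUR2, ICL, EIN3 and LTI30 lay closest to the threshold. Between 36.2% and 37.8% of signals per array lay under 16, where folds are bounds.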

Other observations

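The tests of the peroxidase and iron patterns in this part, and the list of jasmonate oxidases, were chosen after the values of several of these genes had been seen. Of the 17 gene families tested beside the report's lists, some of which share genes with those lists, 3 passed camera at its preset correlation and 0 with an estimated one. The plant U-box ligases had 4 of 5 tested members higher, led by PUB23 (3.21-fold) and PUB22 (3.20-fold), with a camera adjusted p of 0.00136 over the families (adjusted p = 0.632 with an estimated correlation); 3 of these genes also belong to the immune signalling list. Of 28 UDP-glycosyltransferases, which attach sugars to small molecules, 11 were higher and 5 lower (camera adjusted p = 0.0133; adjusted p = 0.632 with an estimated correlation); UGT73B4, UGT73B5, UGT74B1, UGT78D2 and UF3GT also belong to the detoxification, indole or flavonoid lists. UGT87A2 rose 5.35-fold from 81.9 ± 0.99 to 438 ± 13 (SD, n = 2), and UGT76B1 rose 2.58-fold, while UGT78D1, a flavonol rhamnosyltransferase, fell 2.06-fold. Serine carboxypeptidase-like genes had 8 of 13 lower and 0 higher (camera adjusted p = 0.0133; adjusted p = 0.647 with an estimated correlation), with falls of 1.93-fold for scpl46 and 1.76-fold for SCPL45. The estimated correlation was 0.52 for the U-box ligases and 0.16 for the carboxypeptidase-like genes, but negative (−0.02) for the UDP-glycosyltransferases. Even so, the unadjusted camera p of the UDP-glycosyltransferases rose from 0.00234 to 0.0755 when it was used. The misses of these families with an estimated correlation therefore cannot show whether correlated genes made the calls. The defensins split, with PDF1.4 at least 4.8-fold higher and LCR68 1.77-fold lower (camera adjusted p = 0.0939). The β-glucosidases did not pass as a family (4 higher and 3 lower of 11, camera adjusted p = 0.162), although BGLU46, which acts on monolignol glucosides, rose 2.67-fold to 185 ± 23 and BGLU45 rose at least 4.1-fold. The wall acetyltransferase family TBL had 7 of 16 lower and 1 higher (camera adjusted p = 0.0968), and the tetraspanins 4 of 7 lower and 1 higher (0.663). The camera adjusted p was 0.739 for the cytochromes P450, 0.667 for ubiquitin-conjugating enzymes, 0.393 for SWEET transporters, 0.823 for AGAMOUS-like factors, 0.600 for IQ67-domain proteins, 0.839 for RALF-like peptides, 0.639 for glutamate receptor-like channels, 0.310 for calmodulin-like proteins, 0.910 for aldehyde dehydrogenases and 0.664 for basic helix-loop-helix factors. Symbols reached only part of some of these families, so the values do not describe them as wholes. The 10 cytochromes P450 tested were CYP71B genes and CYP84A4, and the 6 basic helix-loop-helix factors tested did not include AT1G10585. The jacalin-related lectins named by symbol had 3 genes tested, 1 of them lower, and did not include AT1G52060 and AT1G52070. All 3 jasmonate oxidases measured, which turn jasmonate into an inactive hydroxylated form, were higher: AT5G05600 20.9-fold, AT2G38240 at least 6.2-fold and JRG21 at least 3.3-fold.

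Class III peroxidases, which oxidise phenolics and form or consume hydrogen peroxide in the cell wall, moved both ways, with 11 of 21 tested lower and 6 higher. The falls included AT5G64100, from 1199 to 220 (5.45-fold), and AT4G30170, from 312 to 19.6 (a log2 change of −4.00). The rises included AT5G64120, from 426 to 1845 (4.33-fold), and AT5G39580, from 277 to 1156 (4.14-fold). After quantile normalization 10 of the 11 lower peroxidases were still lower. Their log2 changes ran from −0.36 to −7.79, against median changes by signal of −0.19 to 0.07 over all probe sets tested. Each fall was larger than that shift, so quantile normalization could remove few of them and is no separate test of intensity-dependent scaling. A loss of root tissue from the chitosan samples may be a candidate source, but only 2 of the 28 root markers listed could be measured, PYK10 (3646 and 3510) and NAI2 (800.2 and 849), with a median log2 change of 0.012. Both are also expressed in the hypocotyl or cotyledons of young seedlings, and the root hair expansin EXPA18, of the list fixed in advance, was at least 2.7-fold lower, so root loss cannot be told apart from a change in these genes. Repression of particular peroxidases by chitosan stays open as an untested hypothesis.

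Of 24 listed genes that iron deficiency induces, only 6 could be measured, and 4 of these were higher. AT1G47400, which encodes an iron-deficiency signalling peptide, rose 9.28-fold from 91.2 to 847, BHLH101 rose at least 4.5-fold, AT5G05250 rose 3.59-fold and PYE rose from 32.9 to 76.0, while AT3G07720 and F6H1 were not called, with log2 changes of −0.31 and −0.26. After quantile normalization the 4 genes were still called higher and the median log2 change of all 6 was 1.63. Each of the 4 rises was larger than the median changes by signal over all probe sets tested. Quantile normalization could therefore hardly remove these calls and is no separate test of intensity-dependent scaling here either. Less iron available to the treated seedlings is a candidate explanation, since chitosan is known to bind metal ions. It needs iron-storage and other iron-sufficiency genes to fall, but only 1 of the 8 listed, SAPX, could be measured, with a log2 change of 0.20 (adjusted p = 0.187), and the 4 induced genes other than AT1G47400 and BHLH101 went both ways. Lower iron availability therefore cannot be told apart from an induction of these genes by other routes.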
